A study of Mus musculus with 36 samples.

How the data were processed

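Flow-sorted cardiac macrophages of 36 libraries were profiled by polyA RNA sequencing. Per the labels' protocols, double-stranded cDNA was made with the SMARTer Ultra Low kit from 1 to 50 ng of total RNA with an integrity number above 8, fragments were amplified for 12 cycles, and single reads of 50 bases were sequenced on a HiSeq-3000 without strand information. The submitters' processing notes name Bowtie2, TopHat, TopHat2 2.0.10, HTSeq, DESeq and edgeR and the build GRCm38, with no parameters. The authors deposited 1 table of raw, whole-number read counts per gene. Its name calls it filtered, by a filter not given in the sources. It lists 12795 genes, of which 11975 are protein coding, and in each of them the library with the fourth highest value reached at least 1.01 CPM. Genes below that level were not analysed here. Columns were matched to samples by name, and groups follow the labels (genotype, CCR2 fraction and Cre status). Positions come from GENCODE vM21 (GRCm38), matched by Ensembl identifier.

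CPM (counts scaled to library size) and log2 values were computed here from the deposited counts. Of the counts of a library 13.9 to 18.4% fell on the 10 most abundant genes and 0.460 to 1.30% on mitochondrial genes. At this depth the spread between libraries, a common dispersion of 0.0943, and not counting error set the precision for genes of 10 CPM or more. In all 64 pairs of libraries within a group the counts differed by more than sampling noise (chi-square per degree of freedom of 20.3 to 121), so each library was counted once. Intervals of counts treat reads as independent molecules, since the libraries carried no molecular identifiers.

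The main test was edgeR 4.0.16's quasi-likelihood F-test (R 4.3.3) with TMM normalization, 1 fit of 8 group means over 36 libraries and Benjamini-Hochberg adjustment. The edgeR expression filter (minimum count 10) removed none of the 12795 genes. A standard error is the log2 fold change divided by the square root of F. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and beside it with camera at an estimated correlation and with fry, adjusted over the 25 lists of a comparison. The lists held 441 members, of which 427 were measured. Pathway lists were lysosomal hydrolases, lysosomal membrane and v-ATPase, autophagy, TFE family and mTORC1 feedback, lipid handling, inflammatory cytokines and NF-kB, interferon response, MHC class II presentation, repair and growth factors, efferocytosis and complement, proliferation, glycolysis and oxidative phosphorylation. Cell state lists were resident cardiac macrophage and monocyte and monocyte-derived, the quality list was dissociation and stress response, and the 9 lists of other cell types were cardiomyocyte, fibroblast, endothelial, mural, neutrophil, T and NK cell, B cell, dendritic cell and erythroid. Overlaps of calls were tested with Fisher's exact test, two-sided.

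Comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. By that rule the text names Tfeb, Cx3cr1 and Ccr2 in every comparison and Lipa, Gpnmb, Sqstm1, Lamp1, Mcoln1 and Ctsd in the TFEB comparisons. It further takes the 8 called genes with the largest increase and the 8 with the largest decrease per comparison, with a mean of at least 10 CPM in a group, without unnamed gene models and pseudogenes. Per list it takes up to 4 members with the smallest unadjusted p in the TFEB comparisons and up to 2 in the others, of which part is named. A result on 1 gene within the rule is not reported here. Genes outside the rule are said to be named after their values were seen.

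Each label number within a genotype occurs in 4 libraries, and the labels do not say that these came from 1 animal. Pairing was checked on deviations from group means before any blocked fit was looked at. Within a genotype the smallest correlations of same-numbered pairs were 0.142 and 0.371 between fractions (CX3CR1-Cre and mac-TFEB), 0.135 and 0.240 between CX3CR1-Cre and Cre-neg (CCR2neg and CCR2pos) and 0.276 and 0.300 between mac-TFEB and TFEB-TG Cre-neg. Pairs that differ in both fraction and Cre status reached down to 0.0899, with a mean of 0.330 over all kinds. All 9 labels had Xist, at a limit of 10 CPM, in all 4 of their libraries or in none. The label was therefore used as a block (9 levels) in the comparisons within a genotype and in the differences of differences, and is called the animal block.

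Alternatives were DESeq2 size factors, a stricter filter (1 CPM in 9 libraries, 12120 genes), no filter, DESeq2 1.42.0's Wald test, limma-voom with quality weights, a random effect of genotype and number (correlation 0.266), the blocks, a fit to the libraries of a comparison alone, other rules for removing cassette calls and leaving out each library in turn. A sex term read from Xist, a fit to libraries with Xist alone, a fit without the 2 libraries that stood apart and list tests with the block were added after seeing the data, as was a comparison of mac-TFEB with TFEB-TG Cre-neg. The libraries that stood apart were TFEB-TG CCR2neg Cre-neg 1, with cardiomyocyte transcripts, and CCR2neg CX3CR1-Cre 3, on the fourth principal component.

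Tests were run on simulated counts for 12795 genes, 50 changed at each fold. For the TFEB effect in CCR2neg cells edgeR recovered 36, 48, 66 and 78% at 1.5, 2, 3 and 4-fold, with 8 false among 122 calls, and 42, 54, 66 and 82% with the number as a block, with 48 false among 170. For the effect beyond the cassette in CCR2neg cells it recovered 4, 20, 48 and 60% (1 false of 67) and 20, 48, 58 and 62% with the animal block (5 false of 99). In both, each list test called 10 of 10 changed and 0 of 90 unchanged lists. Camera called up to 20 in regrouped real libraries, so that 0 may not carry over.

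Without strand, reads of overlapping genes cannot be told apart, so the values of genes that share at least 10% of their exon bases with another gene are uncertain. Those named are Cfb (79.5% shared with Gm20547), S100a4 (51.7%, Gm42674), Duoxa2 (42.8%, Duoxa1), Ctsd (34.4%, Gm49369), Kif20a (29.3%, Cdc23), Ctsl (26.8%, Gm47123), Tcim (18.7%, Gm26714), Sqstm1 (17.3%, Mrnip), Pkm (15.3%, Gm49759), Tgm2 (13.7%, Gm20412), Ctsb (12.8%, Fdft1), Cd9 (10.7%, Gm26728) and H2-DMa (10.4%, Brd2). Values of multigene families (H2, Cd209, Sirpb1, Clec4b, Ms4a4 and tryptase genes) depend on how the authors' counting treated reads that match several genes. Some log2 values that end in 0 have 1 decimal. Figures were drawn with matplotlib 3.10.9.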

Results

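Macrophages were sorted by flow cytometry from mouse hearts, and polyA RNA of 36 libraries was sequenced. Tamoxifen was given for 7 days, the heart was made ischemic for 90 min, and cells were collected 7 days later. Sorting on CCR2, the chemokine receptor through which monocytes leave the bone marrow, gave a CCR2-positive (CCR2pos) and a CCR2-negative (CCR2neg) fraction. TFEB-TG animals carried an expression cassette for TFEB, a transcription factor of lysosome and autophagy genes, behind a stop sequence that Cre recombinase removes, and TFEB-wt animals carried no cassette. Within each genotype and fraction there was a group without Cre (Cre-neg) and a group with Cre, which is called mac-TFEB in TFEB-TG and CX3CR1-Cre in TFEB-wt. Each of the 4 TFEB-TG groups held 4 libraries and each of the 4 TFEB-wt groups held 5. All animals are described in the labels as carrying a Cre driven by Cx3cr1 and a Td-Tomato reporter, so what set Cre-neg cells apart is not given in the sources used here. The labels also do not say that libraries of a group came from separate animals, and p-values then measure the spread between these samples, which may be technical in part, though libraries with and without Xist in each group point to at least 2 animals. Total counts ran from 13797484 to 32645783 per library, with a median of 19676040, and 12359 to 12780 of the 12795 listed genes were detected in each. Below, a value written as a number ± another is a log2 fold change with its standard error, and a gene is called at an adjusted p under 0.05 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjustment over 12795 genes).

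Tfeb (ENSMUSG00000023990, chromosome 17, 47737030 to 47792419, GRCm38) was counted at 188 ± 127 CPM (counts scaled to library size, mean ± SD, n = 4) in CCR2neg mac-TFEB libraries and at 7.91 ± 0.920 (n = 5) in CCR2neg CX3CR1-Cre libraries. In CCR2pos cells the values were 158 ± 111 (n = 4) and 6.54 ± 2.94 (n = 5). Single mac-TFEB libraries spread from 67.4 to 335 CPM in CCR2neg cells and from 60.4 to 279.8 in CCR2pos cells. Tfeb was also above the TFEB-wt level in the TFEB-TG Cre-neg libraries, at 21.1 ± 10.6 against 6.65 ± 2.48 CPM in CCR2neg cells and 38.8 ± 15.2 against 6.06 ± 0.770 in CCR2pos cells (SD, n = 4 and 5). The counts do not separate transcripts of the cassette from those of the endogenous gene. Ccr2 (ENSMUSG00000049103, chromosome 9, 124101950 to 124113557) averaged 729.9 CPM in CCR2pos and 47.2 CPM in CCR2neg CX3CR1-Cre libraries, which follows the sort. Xist, the transcript of the inactive X chromosome, was read in every library of the labels TFEB-TG 3 and 4 and TFEB-wt 2 to 5 and in none of TFEB-TG 1 and 2 and TFEB-wt 1. The share of labels with Xist was thus 2 of 4 in TFEB-TG and 4 of 5 in TFEB-wt.

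**Figure D1:**
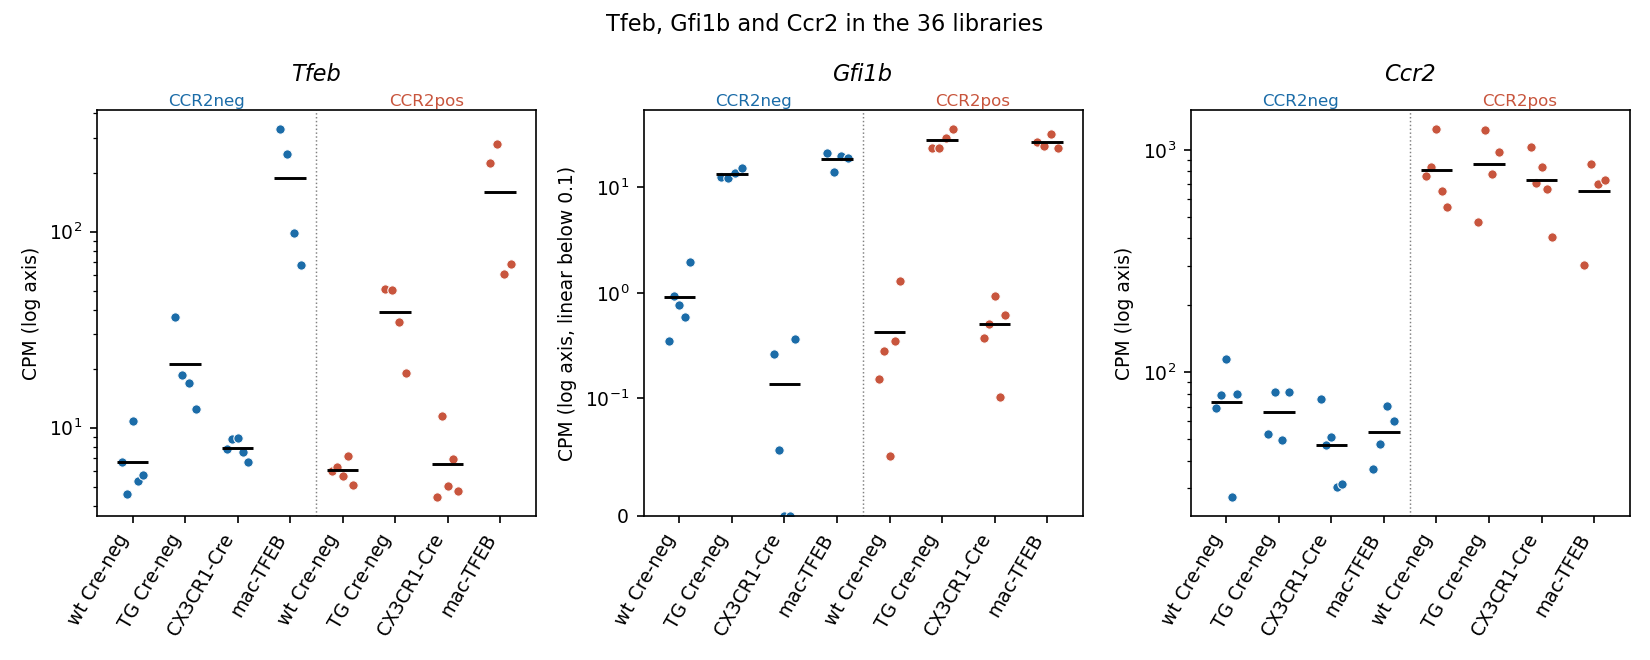
Levels of Tfeb, Gfi1b and Ccr2 in each of the 36 libraries, in CPM on a log axis (linear below 0.1 for Gfi1b), by group, with points for libraries and lines for group means. Tfeb averaged 188 CPM in CCR2neg mac-TFEB libraries, Gfi1b was above 1 CPM chiefly in the TFEB-TG groups, and Ccr2 separated the sorted fractions.

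The Cre-neg libraries were compared to find mRNAs that differ with the TFEB-TG cassette alone. In CCR2neg cells, 4 TFEB-TG against 5 TFEB-wt libraries, Gfi1b was the largest change, at 3.88 ± 0.47. It encodes a zinc-finger repressor of the red-cell and platelet lineages. Its neighbors on chromosome 2 were lower, with Gtf3c5, a subunit of the RNA polymerase III factor TFIIIC, at -1.32 ± 0.17 and Mrps2, a protein of the mitochondrial ribosome, at -1.16 ± 0.17. MHC class II genes, which encode the molecules that present peptides to helper T cells, fell in part: H2-Ab1 (-1.06 ± 0.25), H2-Eb1 (-1.0 ± 0.23), H2-Aa (-0.73 ± 0.16) and H2-DMb1 (-0.51 ± 0.12) were called among 10 measured list members. Cell-division genes rose in 2 cases, the kinetochore motor Cenpe (1.13 ± 0.23) and the mitotic kinesin Kif20a (0.97 ± 0.22), whose exons overlap those of Cdc23 on the other strand.

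The remaining genes named by rule in the CCR2neg cassette comparison were Phactr2 (1.45 ± 0.34), a regulator of phosphatase and actin, which rose, and Sdf2l1 (-1.07 ± 0.22), Arhgef10l (-1.04 ± 0.24), Urgcp (-1.01 ± 0.22) and Pigx (-0.94 ± 0.21), which fell. Sdf2l1 is part of a chaperone complex of the endoplasmic reticulum and Pigx takes part in building GPI anchors. Adjusted p of the 14 genes called and named ran from 1.8e-05 to 0.0489 (edgeR, Benjamini-Hochberg). Tfeb itself was at 1.65 ± 0.43 and missed the threshold (edgeR adjusted p = 0.0697), as did Cx3cr1, the fractalkine receptor gene, at 0.17 ± 0.20 and Ccr2 at -0.16 ± 0.34. Of the 25 gene lists, camera called 3. MHC class II presentation was lower with a median of -0.50 (camera adjusted p = 1.4e-08, adjusted p = 0.300 with an estimated correlation), with 6 genes lower when adjusted over the list alone against 4 over all genes. The proliferation list was higher with a median of 0.70 (camera adjusted p = 2.4e-12, adjusted p = 0.410 with an estimated correlation), with 13 of 22 genes higher when adjusted over the list alone and 0 over all genes (edgeR). Cardiomyocyte transcripts were higher with a median of 0.96 (camera adjusted p = 0.00115, adjusted p = 0.817 with an estimated correlation). They came mainly from TFEB-TG CCR2neg Cre-neg library 1, which held 80.3 CPM of the heart myosin gene Myh6 where the other libraries of its group held 0.322 to 1.38.

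In all, 52 of 12795 genes were called for the cassette in CCR2neg cells, 5 higher and 47 lower, and 1671 had an unadjusted p under 0.05 (edgeR's quasi-likelihood test). That count depended on single libraries and was 440, 6 and 22 without TFEB-TG Cre-neg libraries 1, 3 and 4 and 24, 177, 7, 96 and 8 without TFEB-wt Cre-neg libraries 1, 2, 3, 4 and 5. A fit to the 9 libraries of the comparison alone called 1, Gfi1b. It, Gtf3c5 and Mrps2 were called whichever library was left out, and the other 11 of 14 called genes named here were lost in at least 1.

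In CCR2pos cells the cassette comparison called 4 genes, again of 4 against 5 libraries. Gfi1b was 6.08 ± 0.52 and Tfeb was 2.68 ± 0.43, both higher in TFEB-TG, while Gtf3c5 (-1.35 ± 0.17) and Mrps2 (-0.98 ± 0.17) were lower. Adjusted p of the 4 ran from 4.1e-09 to 0.00500 (edgeR, Benjamini-Hochberg), and 393 genes had an unadjusted p under 0.05. Cx3cr1 was at 0.33 ± 0.20 and Ccr2 at 0.10 ± 0.33, neither called. Gfi1b, Gtf3c5 and Mrps2 were the genes called in both fractions, 1 higher and 2 lower, where independent lists of these sizes would share 0.000782 and 0.00735 (Fisher's exact p = 7.8e-04 and 1.3e-05). Both fractions came from the same animal labels, so such lists are not independent here. Gfi1b lies at chromosome 2, 28609450 to 28621982, Gtf3c5 at 28566311 to 28583751 and Mrps2 at 28468066 to 28471178 of that chromosome (GRCm38). In Cre-neg cells Gfi1b averaged 13.4 ± 1.32 CPM in CCR2neg and 27.8 ± 5.65 CPM in CCR2pos TFEB-TG libraries (SD, n = 4) against 0.920 ± 0.619 and 0.426 ± 0.503 in TFEB-wt (SD, n = 5). Mrps2 lost its call without TFEB-TG Cre-neg library 3 (edgeR adjusted p = 0.0940), and the other 3 genes kept theirs whichever library was left out. Of the gene lists, 5 passed camera's preset correlation, led by proliferation with a median of 0.51 (camera adjusted p = 1.0e-16). None of the 5 passed with an estimated correlation, where the smallest adjusted p was 0.349, and resident macrophage, inflammatory, MHC class II and oxidative phosphorylation medians lay between -0.22 and 0.18.

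The main comparison set mac-TFEB against CX3CR1-Cre libraries to find mRNAs that respond to TFEB overexpression. In CCR2neg cells (4 against 5 libraries), Tfeb was 4.57 ± 0.46. The aspartic protease Ctsd was 1.17 ± 0.17, with 11667 ± 3157 CPM in mac-TFEB and 5189 ± 929 in CX3CR1-Cre libraries (SD, n = 4 and 5). Without Cre it was at 10335 ± 2588 in TFEB-TG and 7923 ± 1554 in TFEB-wt cells (SD, n = 4 and 5), so part of the difference lies in lower CX3CR1-Cre controls. Gpnmb, a transmembrane glycoprotein of lysosomes and lipid-laden macrophages, was 2.24 ± 0.43, and Lipa, the lysosomal acid lipase, was 0.58 ± 0.11. MHC class II genes fell, among them the invariant chain gene Cd74 at -1.18 ± 0.19. Adjusted p of these 5 genes ran from 1.1e-07 to 0.00345 (edgeR, Benjamini-Hochberg). The other lysosome and autophagy genes fixed beforehand were not called: the autophagy receptor Sqstm1 was at 0.04 ± 0.12, the membrane glycoprotein Lamp1 at 0.28 ± 0.20 and the calcium channel Mcoln1 at -0.34 ± 0.28. Cx3cr1 (-0.27 ± 0.20) and Ccr2 (0.19 ± 0.34) were not called either.

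**Figure D2:**
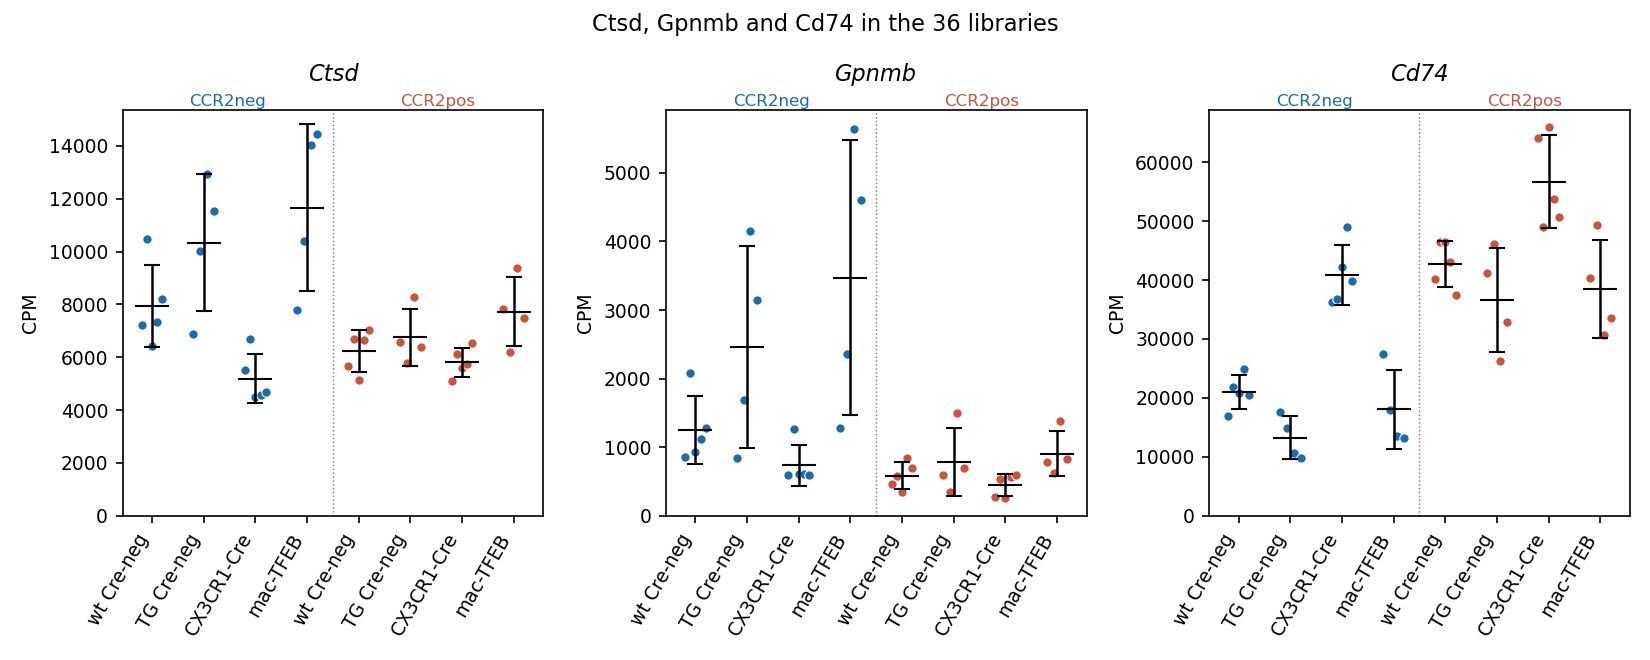
Levels of Ctsd, Gpnmb and Cd74 in each library, in CPM, by group, with points for libraries and the mean and SD of each group. In CCR2neg cells Cd74 averaged 18044 CPM in mac-TFEB against 40829 in CX3CR1-Cre libraries.

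Among the largest increases in CCR2neg mac-TFEB cells were Gfi1b (7.00 ± 0.58), the neuropeptide gene Npy (2.83 ± 0.51) and Cd28 (2.60 ± 0.34), a co-stimulatory receptor known from T cells. Stra6l (2.12 ± 0.37), a homolog of a vitamin A transporter, and Mcoln3 (1.82 ± 0.47), a cation channel of endosomes and lysosomes, rose as well. Of the largest decreases, the mast cell tryptase Tpsb2 was -6.56 ± 1.74, the complement component C6 was -2.74 ± 0.54, the gelatinase Mmp9 was -2.27 ± 0.56 and Plbd1, a phospholipase B-like gene, was -1.38 ± 0.21. Mrps2 (-0.98 ± 0.17) and Gtf3c5 (-1.02 ± 0.17) were lower, as in the Cre-neg comparison. Adjusted p of these 11 genes ran from 1.7e-09 to 0.0484 (edgeR, Benjamini-Hochberg). Cd4, which encodes the helper T cell co-receptor and stood in the T and NK cell list, was 1.39 ± 0.24, and Batf3, a dendritic cell transcription factor, was -1.08 ± 0.19, each the only called member of its list.

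Of 35 lysosomal hydrolases, Ctsd, Lipa and the cysteine protease Ctsb (0.54 ± 0.12) rose and none fell, with 6 higher when adjusted over the list alone. The list's median was 0.13 (camera adjusted p = 0.0176, adjusted p = 0.644 with an estimated correlation). Of 25 lysosomal membrane and v-ATPase genes, the proton pump subunits Atp6v1a (0.51 ± 0.11) and Atp6v0a1 (0.46 ± 0.11) and the cholesterol transporter Npc1 (0.39 ± 0.09) rose, 6 when adjusted over the list alone, with a median of 0.07 (camera adjusted p = 0.00616, adjusted p = 0.527 with an estimated correlation). Of 25 lipid handling genes, the lipid droplet coat gene Plin2 (0.73 ± 0.14), the cholesterol esterification enzyme Soat1 (0.67 ± 0.14) and the fatty acid-binding gene Fabp5 (1.45 ± 0.38) rose, and 6 were higher and 1 lower when adjusted over the list alone. Its median was 0.18 (camera adjusted p = 0.00616, adjusted p = 0.0687 with an estimated correlation, fry adjusted p = 0.00326). In the TFE family and mTORC1 feedback list, Gpnmb and Fnip2 (1.02 ± 0.19), a folliculin-interacting gene, rose among 15, and in the autophagy list Atg7 (0.45 ± 0.12), an enzyme of autophagosome formation, rose among 30. Neither list passed camera (adjusted p = 0.205 and 0.939), and adjusted over the list alone they held 3 higher and 3 lower, and 1 higher and 1 lower.

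Of 10 MHC class II presentation genes, 7 fell, both over all genes and when adjusted over the list alone. They were H2-Aa (-1.20 ± 0.16), H2-Ab1 (-1.44 ± 0.25), H2-Eb1 (-1.38 ± 0.23), the peptide-loading genes H2-DMa (-0.73 ± 0.11) and H2-DMb1 (-0.83 ± 0.12), Cd74, and Ciita (-1.0 ± 0.22), the transactivator of the others. This list's median was -0.92, and it was the 1 list of the 9 called by camera in this comparison that also passed with an estimated correlation (camera adjusted p = 4.7e-20, adjusted p = 0.00585 with an estimated correlation, fry adjusted p = 6.5e-05). Cd74 averaged 40829 ± 5130.0 CPM in CX3CR1-Cre (n = 5) and 18044 ± 6644 in mac-TFEB libraries (n = 4), beside 20998 ± 2855 and 13251 ± 3617 in the TFEB-wt and TFEB-TG Cre-neg libraries of this fraction (SD). The dendritic cell and B cell lists, whose cells also carry MHC class II, had medians of 0.34 and -0.15 and were not called (camera adjusted p = 0.326 and 0.238).

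Proliferation genes were higher in CCR2neg mac-TFEB cells by a median of 0.74 (camera adjusted p = 2.3e-12, adjusted p = 0.218 with an estimated correlation). The mitotic kinase Aurka (0.82 ± 0.20) and the ribonucleotide reductase subunit Rrm2 (1.05 ± 0.28) rose among 22, and 13 were higher when adjusted over the list alone. Of 19 glycolysis genes, the phosphofructokinase Pfkp (0.45 ± 0.11) rose, 5 were higher and 1 lower when adjusted over the list alone, and the median was 0.18 (camera adjusted p = 0.0322, adjusted p = 0.644 with an estimated correlation). The repair and growth factor list held the growth factor Hgf (0.89 ± 0.20) and the macrophage elastase Mmp12 (1.43 ± 0.38), which rose, and Mmp9, which fell, among 19, with 5 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0665). In the efferocytosis and complement list, the transglutaminase Tgm2 (0.65 ± 0.16) rose and the complement gene C1qa (-0.76 ± 0.20) fell among 18, with 3 higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.944). Of 23 inflammatory cytokine and NF-kB genes, the chemokine Ccl12 (-0.91 ± 0.22) fell, 2 were lower when adjusted over the list alone, and the list was not called (camera adjusted p = 0.326).

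No member of the resident cardiac macrophage list (median -0.45, camera adjusted p = 5.8e-05, adjusted p = 0.373 with an estimated correlation) or of the dissociation and stress response list (median -0.26, camera adjusted p = 1.0e-04, adjusted p = 0.0687 with an estimated correlation) was called by edgeR, though 4 and 3 were lower when adjusted over the list alone. Fibroblast transcripts were lower, with a median of -0.69 (camera adjusted p = 0.0445, adjusted p = 0.708 with an estimated correlation). The other lists were not called by camera. Their medians were -0.15 for interferon response, 0.19 for monocyte and monocyte-derived genes, 0.04 for oxidative phosphorylation, -0.32 for cardiomyocyte, 0.38 for endothelial, 0.56 for mural, 0.48 for neutrophil, 0.58 for T and NK cell and 0.56 for erythroid genes. Camera's direction opposed the median for the oxidative phosphorylation and mural lists.

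**Figure D3:**
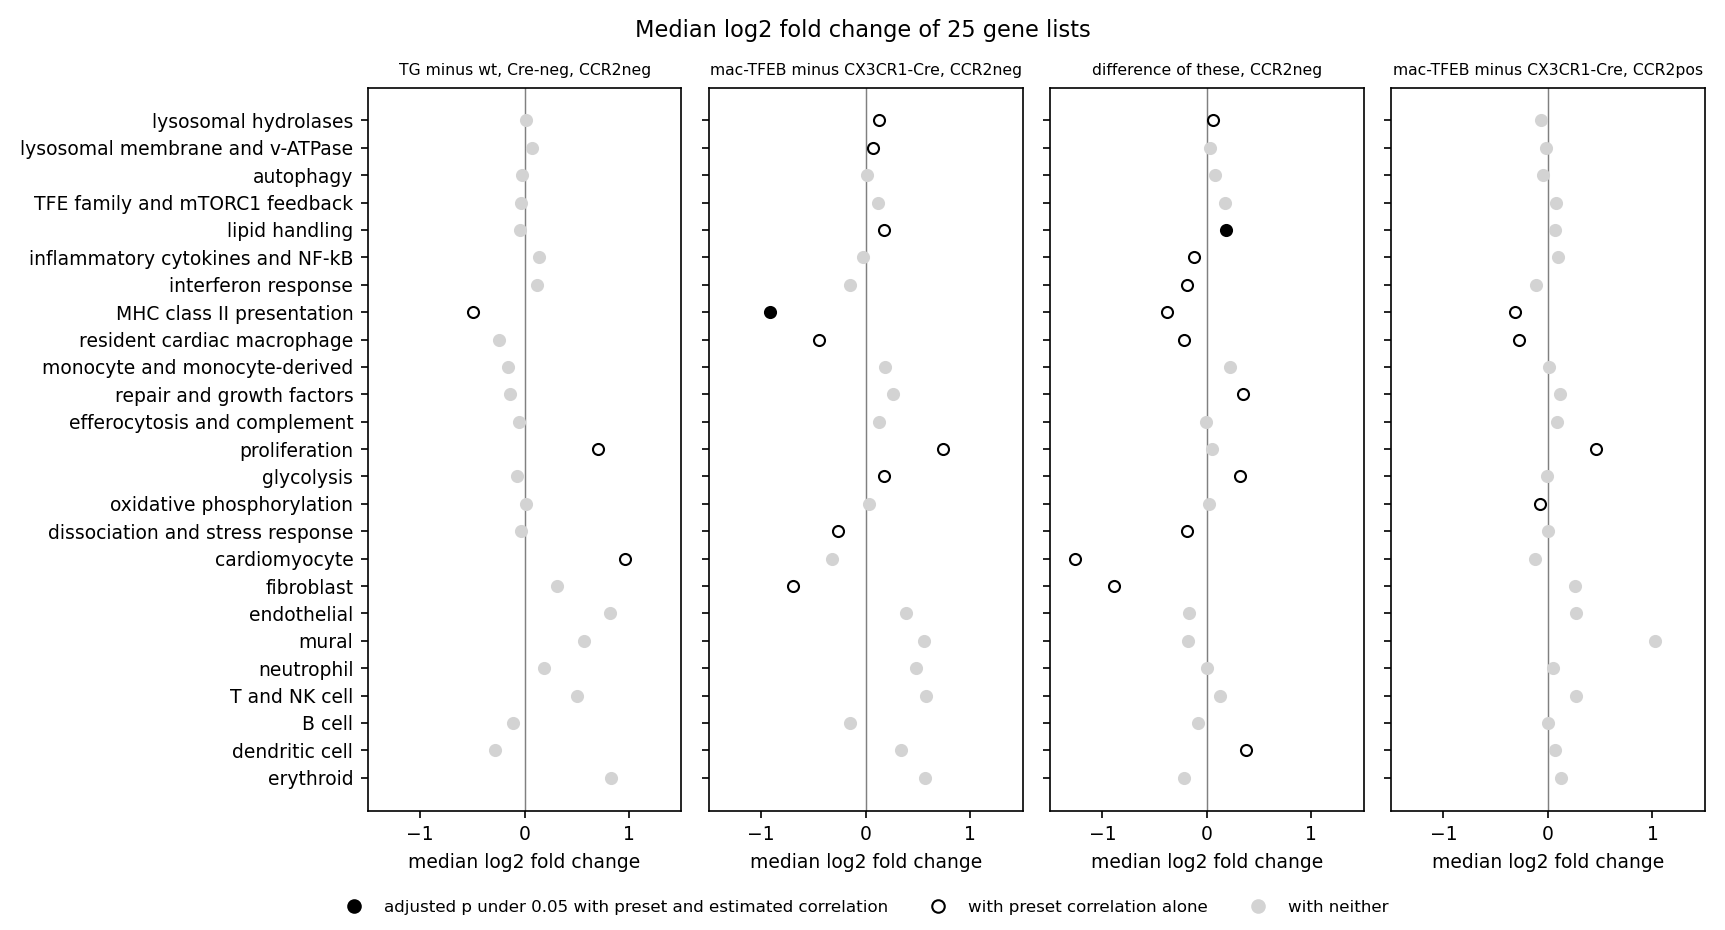
Median log2 fold change of each of the 25 gene lists in 4 comparisons, with black points for lists that camera called with a preset and with an estimated correlation and open points for those called with the preset correlation alone. The MHC class II list stood at -0.92 for mac-TFEB against CX3CR1-Cre and at -0.50 for TFEB-TG against TFEB-wt Cre-neg, both in CCR2neg cells.

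By edgeR's quasi-likelihood test, 176 genes were called for TFEB in CCR2neg cells, 118 higher and 58 lower, with 1873 at an unadjusted p under 0.05. That balance depended on the fit, with 643 and 708 by limma-voom with quality weights, 224 and 204 with a sex term and 404 and 406 in libraries with Xist. Removing the genes called for the cassette alone, as the study's design describes, took out 13 and left 163, of which 116 were higher and 47 lower. The genes taken out included Gfi1b, Mrps2, Gtf3c5, H2-Ab1, H2-Eb1, H2-Aa and H2-DMb1, while Tfeb, Ctsd, Gpnmb, Lipa and Cd74 stayed. The cassette and TFEB calls shared 2 higher and 11 lower genes, where independent lists would share 0.0461 and 0.213 (Fisher's exact p = 8.3e-04 and 9.4e-17), and 164 of the 176 TFEB calls had the same sign in the cassette comparison. Both comparisons drew on the same animal labels, so their calls are not independent. When the cassette list was drawn at an unadjusted p under 0.05 instead, 97 genes were left. The number of TFEB calls was 59 and 82 without mac-TFEB libraries 3 and 4 and 95, 107 and 117 without CX3CR1-Cre libraries 3, 4 and 5, and 71 in a fit to the 9 libraries of the comparison alone. Tfeb, Ctsd, Gpnmb, Lipa and Cd74 were among the 21 of 41 called genes named that kept their call whichever library was left out. Atg7, Atp6v0a1, Atp6v1a, Aurka, C1qa, Ccl12, Ciita, Ctsb, Fabp5, Fnip2, Hgf, Mcoln3, Mmp12, Mmp9, Npc1, Pfkp, Rrm2, Soat1, Tgm2 and Tpsb2 lost it in at least 1 fit.

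In CCR2pos mac-TFEB against CX3CR1-Cre cells (4 against 5 libraries), Tfeb was 4.58 ± 0.46 and Gfi1b 5.76 ± 0.52 higher. Mrps2 (-1.17 ± 0.17) and Gtf3c5 (-1.10 ± 0.17) were lower. So was the gene model Gm10134 between them (-1.18 ± 0.24), named after its value was seen. Adjusted p of the 5 ran from 1.3e-08 to 0.0454 (edgeR, Benjamini-Hochberg). The lysosomal genes fixed beforehand were not called here: Ctsd was at 0.41 ± 0.17, Gpnmb at 1.02 ± 0.42, Lipa at 0.02 ± 0.11, Lamp1 at 0.21 ± 0.20, Mcoln1 at 0.17 ± 0.28 and Sqstm1 at 0.13 ± 0.12. Cx3cr1 was at -0.15 ± 0.20 and Ccr2 at -0.16 ± 0.33. MHC class II presentation had a median of -0.31 (camera adjusted p = 2.6e-06, adjusted p = 0.521 with an estimated correlation), with 4 of 10 genes lower when adjusted over the list alone and 0 over all genes (edgeR). Proliferation (median 0.46, adjusted p = 0.521 with an estimated correlation), resident macrophage (median -0.28, adjusted p = 0.760 with an estimated correlation) and oxidative phosphorylation genes (median -0.08, adjusted p = 0.934 with an estimated correlation) were the other lists called by camera's preset correlation. Lysosomal hydrolases had a median of -0.07 (camera adjusted p = 0.177). In all 5 were called and 591 had an unadjusted p under 0.05. Removal of cassette calls, Tfeb among them, left only Gm10134 (-1.01 ± 0.24 for the cassette), or none at an unadjusted cassette p under 0.05. Gm10134 lost its call without mac-TFEB libraries 1 to 4 and CX3CR1-Cre libraries 1, 2, 3 and 5 (edgeR adjusted p 0.0674 to 0.335). The genes called in both fractions were Gfi1b and Tfeb, higher, and Gm10134, Gtf3c5 and Mrps2, lower, against 0.0184 and 0.0136 for independent lists (Fisher's exact p = 8.4e-05 and 8.8e-08).

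Subtracting the cassette difference from the mac-TFEB difference within a fraction gives the TFEB effect beyond the cassette, over 18 libraries each. In CCR2neg cells Tfeb was 2.91 ± 0.61, Ctsd 0.79 ± 0.24, Gpnmb 1.26 ± 0.60, Lipa 0.42 ± 0.16, Sqstm1 0.09 ± 0.17, Lamp1 -0.11 ± 0.29 and Mcoln1 -0.14 ± 0.40. None of them was called, nor were Cx3cr1 (-0.43 ± 0.28) and Ccr2 (0.35 ± 0.48), and edgeR called 0 genes, with 496 at an unadjusted p under 0.05. DESeq2's Wald test called 2 genes, limma-voom with quality weights 0 and a fit with animal label as a random effect 3. With animal label as a block, edgeR called 32 genes, 24 higher and 8 lower. Blocked values were 2.72 ± 0.36 for Tfeb, 0.77 ± 0.16 for Ctsd, 0.69 ± 0.15 for Fnip2, 1.06 ± 0.20 for the galectin Lgals3 and -0.82 ± 0.17 for Ccl12 (edgeR adjusted p of 2.7e-04 to 0.0281). Named after their values were seen, Gfi1b (3.21 ± 0.58), Npy (1.83 ± 0.38), Cd28 (1.71 ± 0.27), the interleukin-7 receptor gene Il7r (1.37 ± 0.28) and the channel gene Mcoln2 (1.34 ± 0.21) were higher in the blocked fit. The membrane gene Tmem176a (-0.63 ± 0.12) was lower. Ctsd, Ccl12 and Tmem176a changed chiefly with Cre in TFEB-wt cells, by -0.61 ± 0.16, 0.71 ± 0.20 and 0.45 ± 0.10, against 0.17 ± 0.18, -0.12 ± 0.22 and -0.18 ± 0.11 in TFEB-TG. The value of Gfi1b rests on TFEB-wt levels near the floor, 0.920 CPM without and 0.138 with Cre, and from TFEB-TG Cre-neg to mac-TFEB cells it was 0.45 ± 0.43 (edgeR adjusted p = 0.906). The blocked count was 8 and 18 without TFEB-TG Cre-neg libraries 3 and 4, 21, 6 and 6 without mac-TFEB libraries 2, 3 and 4, 11, 16 and 8 without TFEB-wt Cre-neg libraries 2, 3 and 5 and 21, 11, 9 and 5 without CX3CR1-Cre libraries 2, 3, 4 and 5.

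Lipid handling genes were higher beyond the cassette in CCR2neg cells, with a median of 0.18 (camera adjusted p = 2.6e-05, adjusted p = 0.00503 with an estimated correlation, fry adjusted p = 0.00668). Adjusted over the list alone, 2 of 25 were higher and over all genes 0 (edgeR). The list's mean log2 CPM was 7.08 without and 7.10 with Cre in TFEB-TG cells and 7.17 and 6.87 in TFEB-wt cells, so the difference comes chiefly from a fall in TFEB-wt. The other 11 lists called by camera were not called with an estimated correlation. They were lysosomal hydrolases (median 0.06, adjusted p = 0.472 with an estimated correlation), repair and growth factors (0.35, adjusted p = 0.120), glycolysis (0.32, adjusted p = 0.247) and dendritic cell genes (0.37, adjusted p = 0.247), all higher. Lower were MHC class II (-0.38, adjusted p = 0.266 with an estimated correlation), interferon response (-0.19, adjusted p = 0.462), inflammatory (-0.13, adjusted p = 0.525), resident macrophage (-0.22, adjusted p = 0.462) and dissociation genes (-0.19, adjusted p = 0.247). Cardiomyocyte (-1.26, adjusted p = 0.247 with an estimated correlation) and fibroblast genes (-0.89, adjusted p = 0.462) were lower too, with the Myh6-rich TFEB-TG Cre-neg library 1 on the side subtracted. With the animal block, camera also called lysosomal membrane and v-ATPase genes (median 0.02, camera adjusted p = 0.0207, adjusted p = 0.313 with an estimated correlation).

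Beyond the cassette in CCR2pos cells, Tfeb was 1.91 ± 0.60, Gpnmb 0.60 ± 0.60, Ctsd 0.30 ± 0.24, Lipa 0.03 ± 0.16, Mcoln1 0.31 ± 0.40, Lamp1 0.11 ± 0.29, Sqstm1 0.08 ± 0.17, Ccr2 -0.26 ± 0.47 and Cx3cr1 -0.48 ± 0.28, none called. EdgeR called 0 genes, with 145 at an unadjusted p under 0.05, and 0 with the animal block, with 351. DESeq2, limma-voom with quality weights and the random-effect fit called 0 as well. Interferon response genes (median -0.15, camera adjusted p = 0.0124, adjusted p = 0.894 with an estimated correlation) were lower and mural genes (median 1.03, camera adjusted p = 0.0442, adjusted p = 0.894 with an estimated correlation) higher. The blocked count was 1 without mac-TFEB library 4 and 1 without CX3CR1-Cre library 2. The animal block added inflammatory (0.0394), MHC class II (0.0187) and endothelial genes (0.0412) by camera adjusted p, with adjusted p of 0.666, 0.666 and 0.755 with an estimated correlation.

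Whether the TFEB effect differed between the fractions was tested as the CCR2pos effect minus the CCR2neg effect. Tfeb differed by 0.02 ± 0.59, so the overexpression itself was within 1 SE of equal. Ctsd was -0.76 ± 0.24, Gpnmb -1.22 ± 0.60 and Lipa -0.55 ± 0.16 in the direction of a smaller effect in CCR2pos cells, and none of the 3 was called. Mcoln1 (0.51 ± 0.40), Lamp1 (-0.07 ± 0.29), Sqstm1 (0.09 ± 0.17), Ccr2 (-0.36 ± 0.47) and Cx3cr1 (0.12 ± 0.28) were not called either. EdgeR called 0 genes, with 505 at an unadjusted p under 0.05, and DESeq2, limma-voom with quality weights and the random-effect fit called 0. With the animal block the count was 0 as well, with 1097 unadjusted, and the smallest edgeR adjusted p was 0.0562 for the receptor gene Cd200r4, named after its value was seen. That blocked count was 7 and 1 without CCR2neg mac-TFEB libraries 1 and 2, 14 without CCR2pos mac-TFEB library 1, 1 without CCR2neg CX3CR1-Cre library 1 and 1 without CCR2pos CX3CR1-Cre library 2.

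MHC class II presentation had the smallest camera adjusted p among the lists, with a median of 0.56 and 7 of 10 genes higher when adjusted over the list alone, 0 over all genes (camera adjusted p = 1.2e-08, adjusted p = 0.0874 with an estimated correlation). With the animal block its adjusted p was 0.0243 with an estimated correlation and 0.00622 by fry. Dissociation genes (0.31, adjusted p = 0.0827 with an estimated correlation) and fibroblast genes (0.73, adjusted p = 0.827) were higher in the difference. Lysosomal hydrolases (-0.19, adjusted p = 0.547 with an estimated correlation), lysosomal membrane genes (-0.11, adjusted p = 0.547), lipid handling (-0.15, adjusted p = 0.0874) and glycolysis genes (-0.19, adjusted p = 0.547) were lower, all 7 being called by camera's preset correlation. The block added inflammatory, proliferation and mural genes by camera (adjusted p = 0.0145, 0.00208 and 0.00540, each 0.266 with an estimated correlation).

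The sorted fractions were compared in CX3CR1-Cre libraries, 5 CCR2pos against 5 CCR2neg. Ccr2 was 3.95 ± 0.36, as the sort sets it. Among the genes higher in CCR2pos cells were the lectin Cd209a (2.62 ± 0.52), the dipeptidyl peptidase Dpp4 (1.67 ± 0.34), the chemokine Ccl8 (1.95 ± 0.38) and the complement factor Cfb (1.47 ± 0.35). Cfb shares most exon bases with Gm20547. Spon1 (2.53 ± 0.54), a matrix protein, Flrt3 (1.79 ± 0.35), an adhesion protein, and Sirpb1a (1.47 ± 0.19), of a family of near-identical receptors, rose too. Higher in CCR2neg cells were the bone-matrix protease Ctsk (-3.66 ± 0.50), the B cell attractant Cxcl13 (-1.86 ± 0.45), the B cell survival factor Tnfsf13b (-0.88 ± 0.21) and Tcim (-1.61 ± 0.37), Sgce (-1.51 ± 0.37), Cdr2 (-1.25 ± 0.26), Spats2 (-1.0 ± 0.24) and Tm7sf3 (-0.80 ± 0.16). Adjusted p of these 16 genes ran from 1.5e-08 to 0.0421 (edgeR, Benjamini-Hochberg), and Tfeb (-0.26 ± 0.41) and Cx3cr1 (0.00 ± 0.19) were not called.

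Of 10 dendritic cell genes, Cd209a, Dpp4 and the growth factor receptor Flt3 (1.69 ± 0.40) rose in CCR2pos CX3CR1-Cre cells, 4 when adjusted over the list alone, with a median of 0.30 (camera adjusted p = 0.00168, adjusted p = 0.143 with an estimated correlation, 0.0329 in the same test with the animal block). MHC class II genes were higher by a median of 0.47 (camera adjusted p = 1.7e-08, adjusted p = 0.143 with an estimated correlation, 0.0329 with the block). None of its 10 members was called over all genes, 5 were higher when adjusted over the list alone, and H2-Aa was 0.55 ± 0.15 (edgeR adjusted p = 0.0734, 0.00160 with the block). Ms4a4c (1.06 ± 0.22) rose in the monocyte list (median 0.17, camera adjusted p = 0.00107, adjusted p = 0.533 with an estimated correlation), of which 5 were higher when adjusted over the list alone. The cytokine Osm (0.57 ± 0.11), the ErbB ligand Nrg1 (2.62 ± 0.58) and the scavenger receptor Scarf1 (1.09 ± 0.25) rose in lists that camera did not call. The resident macrophage receptor Vsig4 was at -1.76 ± 0.46 (edgeR adjusted p = 0.0576, 1.7e-05 with the block). Interferon (median 0.26, adjusted p = 0.533 with an estimated correlation), inflammatory (0.15, adjusted p = 0.533), B cell (0.39, adjusted p = 0.533) and lysosomal hydrolase genes (0.14, adjusted p = 0.571) passed camera's preset correlation as higher. Ctsk fell, and the mean of the hydrolases was -0.01. Fibroblast (-1.05, adjusted p = 0.533 with an estimated correlation), endothelial (-1.38, adjusted p = 0.657) and mural genes (-1.39, adjusted p = 0.533) passed as lower.

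EdgeR called 102 genes between the fractions in CX3CR1-Cre cells, 76 higher in CCR2pos and 26 lower (1412 at an unadjusted p under 0.05), and 552 with the animal block, 345 higher and 207 lower. The unblocked count was 62, 46 and 55 without CCR2neg CX3CR1-Cre libraries 2, 3 and 5 and 58, 57 and 60 without CCR2pos CX3CR1-Cre libraries 1, 2 and 3, and the blocked count was 366 without CCR2neg CX3CR1-Cre library 3. In the unblocked fits 8 of the 21 called genes named kept their call whichever library was left out. Cdr2, Cfb, Cxcl13, Dpp4, Flt3, Ms4a4c, Nrg1, Scarf1, Sgce, Spats2, Spon1, Tcim and Tnfsf13b did not. Without the 2 libraries that stood apart, TFEB-TG CCR2neg Cre-neg 1 and CCR2neg CX3CR1-Cre 3, the unblocked count was 50.

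In mac-TFEB cells (4 CCR2pos against 4 CCR2neg libraries) Ccr2 was 3.60 ± 0.39, and MHC class II genes were higher in the CCR2pos fraction. H2-Ab1 (1.39 ± 0.26), H2-Eb1 (1.35 ± 0.24), H2-Aa (1.24 ± 0.17) and H2-DMb1 (0.89 ± 0.13) were among 7 called of 10, with 8 higher when adjusted over the list alone and a median of 0.99 (camera adjusted p = 8.3e-36, adjusted p = 1.2e-04 with an estimated correlation). Clec4b1 (1.72 ± 0.18), a lectin with a close paralog, Ccl8 (1.96 ± 0.42), Sirpb1a (1.52 ± 0.22), Ms4a4c (1.49 ± 0.25) and Plbd1 (1.45 ± 0.22) were higher as well. Npy (-2.55 ± 0.54), Gpnmb (-1.94 ± 0.46) and Mmp12 (-1.91 ± 0.41) were lower in CCR2pos cells, and the CCR2neg mac-TFEB libraries they were compared with also enter the TFEB comparison above. The phagocytosis bridge Mfge8 (-1.13 ± 0.24), the fatty acid receptor Cd36 (-0.94 ± 0.20), the aminopeptidase Anpep (-1.24 ± 0.27), the tetraspanin Cd9 (-1.11 ± 0.27), Il7r (-1.28 ± 0.26) and the ubiquitin ligase gene Fbxo32 (-1.13 ± 0.25) fell too. Adjusted p of these genes ran from 5.3e-07 to 0.0498 (edgeR, Benjamini-Hochberg). Ctsd was at -0.60 ± 0.18 (edgeR adjusted p = 0.158, 0.00517 with the animal block), Lipa at -0.41 ± 0.12 (0.123, 0.0171 with the block) and Ctsk at -2.08 ± 0.52 (0.0561, 2.6e-04 with the block). Gpnmb lost its call without CCR2neg mac-TFEB libraries 3 and 4 and CCR2pos mac-TFEB libraries 1, 2 and 4 (edgeR adjusted p of 0.101 to 0.191), and Lipa was called without CCR2neg mac-TFEB library 1 (edgeR adjusted p = 0.0285). Tfeb (-0.24 ± 0.43) and Cx3cr1 (0.11 ± 0.21) were not called.

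The dissociation and stress response list was higher in CCR2pos mac-TFEB cells, with Ier3 (0.47 ± 0.11) called of 19, 5 when adjusted over the list alone, and a median of 0.34 (camera adjusted p = 2.4e-08, adjusted p = 0.00527 with an estimated correlation). Osm (0.74 ± 0.12) rose in the repair list. Higher by the preset correlation were inflammatory (median 0.26, adjusted p = 0.179 with an estimated correlation, 0.00716 with the animal block), B cell (0.55, adjusted p = 0.179, 0.00850 with the block) and dendritic cell genes (0.32, adjusted p = 0.112, 0.0295 with the block). Interferon (0.27, adjusted p = 0.228 with an estimated correlation) and monocyte genes (0.13, adjusted p = 0.231) were higher and glycolysis genes (-0.14, adjusted p = 0.688) lower. The block added lysosomal hydrolases, lipid handling and proliferation as lower by camera (adjusted p = 0.0389, 0.0318 and 0.00454), with adjusted p of 0.694, 0.245 and 0.245 with an estimated correlation. EdgeR called 69 genes, 50 higher in CCR2pos and 19 lower (1082 unadjusted), and 481 with the block, 302 higher and 179 lower. The unblocked count was 37 without CCR2neg mac-TFEB library 3 and 36 and 37 without CCR2pos mac-TFEB libraries 2 and 4. The blocked count was 291, 317 and 278 without CCR2neg mac-TFEB libraries 2, 3 and 4 and 295 without CCR2pos mac-TFEB library 4. In the unblocked fits 10 of the 21 called genes named kept their call whichever library was left out. Anpep, Ccl8, Cd36, Cd9, Fbxo32, Gpnmb, Ier3, Il7r, Mfge8, Mmp12 and Npy did not. The comparisons of fractions in CX3CR1-Cre and mac-TFEB cells shared 23 higher and 2 lower genes, where independent lists would share 0.297 and 0.0386 (Fisher's exact p = 1.5e-39 and 6.6e-04).

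Cre-expressing and Cre-neg cells of TFEB-wt animals were compared to see what differs without the cassette. In CCR2neg cells (5 CX3CR1-Cre against 5 Cre-neg libraries) Cx3cr1 was 1.02 ± 0.19 and Duoxa2, a maturation factor of a hydrogen peroxide-producing oxidase whose exons overlap Duoxa1 on the other strand, was 4.4 ± 0.50. MHC class II genes rose in CX3CR1-Cre cells, with Cd74 at 0.96 ± 0.18, H2-DMb1 at 0.79 ± 0.11 and H2-DMa at 0.67 ± 0.10. Monocyte and wound repair genes fell, among them the haptoglobin gene Hp (-2.83 ± 0.56), the lubricin gene Prg4 (-3.00 ± 0.48), the fibronectin gene Fn1 (-2.14 ± 0.43) and Arg1 (-2.12 ± 0.51), an arginine-degrading enzyme of alternatively activated macrophages. The collagenase Mmp13 (1.74 ± 0.30), the checkpoint receptor Lag3 (1.51 ± 0.30), the DNA-degrading enzyme Dnase1l3 (1.4 ± 0.30) and Lilra5 (1.48 ± 0.31), Nes (1.79 ± 0.49) and Neurl1a (1.51 ± 0.36) rose. The chemokine Cxcl3 (-2.95 ± 0.44), the lipoxygenase Alox15 (-2.86 ± 0.62), the activin subunit Inhba (-3.75 ± 0.71), the lectins Cd209b (-4.10 ± 1.07) and Cd209f (-2.85 ± 0.78) and the transporter Slco4a1 (-2.64 ± 0.58) fell. Adjusted p of these 21 genes ran from 2.5e-06 to 0.0395 (edgeR, Benjamini-Hochberg). Tpsb2 was 6.54 ± 1.58 (edgeR adjusted p = 0.0165, 0.0543 with the animal block). These 5 CX3CR1-Cre libraries are also the TFEB comparison's controls, so their values enter both with opposite sign.

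Of 10 MHC class II genes, 7 rose in CX3CR1-Cre CCR2neg cells, 7 also when adjusted over the list alone, with a median of 0.80 (camera adjusted p = 1.5e-16, adjusted p = 0.00625 with an estimated correlation). Of 17 monocyte and monocyte-derived genes 8 fell, 12 when adjusted over the list alone, such as Hp and the calcium-binding S100a6 (-0.92 ± 0.18) and S100a4 (-1.09 ± 0.23), with a median of -1.07 (camera adjusted p = 5.0e-12, adjusted p = 0.00889 with an estimated correlation). Of 19 glycolysis genes 8 fell, 13 when adjusted over the list alone, such as Pkm (-0.78 ± 0.15) and Aldoa (-0.68 ± 0.13), with a median of -0.52 (camera adjusted p = 1.9e-10, adjusted p = 0.0311 with an estimated correlation). The repair list (Arg1, Fn1 and Nrg1 at -2.94 ± 0.58, 6 lower when adjusted over the list alone, median -0.35) and the lipid list (Plin2 at -0.48 ± 0.13 and the liver X receptor gene Nr1h3 at -1.30 ± 0.22, 11 lower when adjusted over the list alone, median -0.29) also passed with an estimated correlation (adjusted p = 0.00583 and 0.00271). Lysosomal Ctsd (-0.61 ± 0.16), Ctsl (-0.71 ± 0.15) and Lipa (-0.39 ± 0.11) fell among 35 hydrolases (median -0.08, camera adjusted p = 0.00280, adjusted p = 0.438 with an estimated correlation). Gpnmb was at -0.77 ± 0.40 (edgeR adjusted p = 0.428, 0.0388 with the animal block), and Sqstm1 (0.16 ± 0.11), Lamp1 (-0.19 ± 0.19), Mcoln1 (0.01 ± 0.26), Tfeb (0.24 ± 0.41) and Ccr2 (-0.65 ± 0.32) were not called.

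In other lists of this comparison, Il6 (-1.5 ± 0.42), the prostaglandin synthase Ptgs2 (-0.96 ± 0.25) and Cxcl3 fell and Ccl12 (0.71 ± 0.20) rose among inflammatory genes. That list had a median of 0.12 and a mean of -0.07 and was called higher by camera with the animal block alone (adjusted p = 0.173 without and 0.0221 with it, 0.298 with the block and an estimated correlation). Resident macrophage genes Ccl24 (-1.15 ± 0.28), Fcna (-1.46 ± 0.32) and Cd209f fell (list median -0.18, adjusted p = 0.490 with an estimated correlation). The interferon-induced Mx1 (0.53 ± 0.15) rose (list median 0.31, adjusted p = 0.171 with an estimated correlation), as did Klf6 (0.37 ± 0.10) of the dissociation list (0.26, adjusted p = 0.122). Axl (0.83 ± 0.19), a receptor for dying cells, and Batf3 (0.86 ± 0.18) rose and Tgm2 (-0.67 ± 0.16) and the lymphocyte gene Cd2 (-0.94 ± 0.27) fell in lists not called by camera. Proliferation (median 0.39, adjusted p = 0.425 with an estimated correlation, 0.0147 with the animal block), neutrophil (-1.88, adjusted p = 0.155, 0.0147 with the block), lysosomal membrane (-0.13, adjusted p = 0.370) and oxidative phosphorylation genes (-0.11, adjusted p = 0.445) passed the preset correlation with no called member. EdgeR called 333 genes, 124 higher and 209 lower (1671 unadjusted), and 965 with the block, 436 higher and 529 lower. The unblocked count was 221 and 200 without TFEB-wt Cre-neg libraries 2 and 5 and 195 and 221 without CX3CR1-Cre libraries 4 and 5. Among the 44 called genes named, 26 kept their call whichever library was left out. Arg1, Ccl12, Ccl24, Cd2, Cd209b, Cd209f, Ctsd, Il6, Klf6, Lipa, Mx1, Nes, Neurl1a, Plin2, Ptgs2, Tgm2, Tmem176a and Tpsb2 did not. Ctsd and Lipa lost theirs with an edgeR adjusted p of up to 0.150 and 0.175, both without TFEB-wt Cre-neg library 2.

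In CCR2pos cells of TFEB-wt animals (5 CX3CR1-Cre against 5 Cre-neg libraries), Duoxa2 was the 1 gene called by edgeR, at 4.42 ± 0.50 (edgeR adjusted p = 4.4e-06). Its level was 10.6 ± 1.63 CPM with Cre and 0.465 ± 0.435 CPM without (SD, n = 5 each). Cx3cr1 was at 0.62 ± 0.19 (edgeR adjusted p = 0.574, 0.00108 with the animal block). The monocyte genes Ly6c2 (-2.76 ± 0.64, 0.222 and 0.00347 likewise) and Plac8 (-2.15 ± 0.51, 0.222 and 2.0e-04) were called with the block alone. Tfeb (0.12 ± 0.42), Ccr2 (-0.15 ± 0.31), Ctsd (-0.10 ± 0.16), Lipa (0.04 ± 0.11) and Gpnmb (-0.39 ± 0.40) were not called in either fit. Monocyte genes were lower as a list, with a median of -0.57, with 9 of 17 lower when adjusted over the list alone and 0 over all genes by edgeR (camera adjusted p = 1.8e-14, adjusted p = 0.0134 with an estimated correlation). MHC class II (median 0.33, adjusted p = 0.112 with an estimated correlation, 0.0177 with the block) and proliferation genes (0.32, adjusted p = 0.397, 0.00421 with the block) were higher. Repair (-0.09, adjusted p = 0.104 with an estimated correlation, 0.0113 with the block), lipid (-0.12, adjusted p = 0.112), mural (-1.52, adjusted p = 0.307, 0.0472 with the block), fibroblast (-1.09, adjusted p = 0.701) and endothelial genes (-1.36, adjusted p = 0.701) were lower and dissociation genes (0.11, adjusted p = 0.401) higher by camera's preset correlation. The block added inflammatory genes (camera adjusted p = 0.0708 without and 0.00282 with it, 0.171 with an estimated correlation). With the block 134 genes were called, 83 higher and 51 lower, and 722 had an unadjusted p under 0.05 without it. Leaving out CX3CR1-Cre library 2 gave 2 genes, and the blocked count was 75, 74 and 65 without TFEB-wt Cre-neg libraries 1, 3 and 5 and 89, 80 and 59 without CX3CR1-Cre libraries 1, 3 and 5.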

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

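The list tests and blocked fit of the effect beyond the cassette and of the difference of fractions were planned, the test of the MHC class II list with a sex term was written down before its result was seen, and the others were chosen after.

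Single libraries stood far from their group in 12 of 144 groups tested, where chance gives about 1 in 20. TFEB-wt CCR2pos Cre-neg library 1 had the highest total, 32645783 counts. Library 3 of that group stood apart in Cx3cr1 (173 CPM) and library 5 in Gfi1b (1.30 CPM). Gpnmb was 1267 CPM in CCR2neg CX3CR1-Cre library 2 and Duoxa2 was 1.47 CPM in TFEB-wt CCR2neg Cre-neg library 1. Transcripts of other cell types set TFEB-wt CCR2neg Cre-neg library 4 apart, with mean log2 CPM of 2.84 over cardiomyocyte, 5.16 over fibroblast and 3.07 over endothelial genes. The endothelial list was at -1.82 in CCR2pos CX3CR1-Cre library 3, the mural list at 1.26 in CCR2pos mac-TFEB library 1, the neutrophil list at 2.60 in TFEB-wt CCR2pos Cre-neg library 5 and the erythroid list at 0.94 in CCR2neg mac-TFEB library 1.

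The mac-TFEB difference departed from the cassette difference in 12 lists in CCR2neg cells by camera's test of the difference itself. Medians of that difference were 0.18 for lipid handling, 0.0613 for lysosomal hydrolases, 0.35 for repair, 0.32 for glycolysis, 0.37 for dendritic cell, -0.38 for MHC class II, -0.22 for resident macrophage, -0.19 for interferon, -0.13 for inflammatory, -0.19 for dissociation, -1.26 for cardiomyocyte and -0.89 for fibroblast genes. In CCR2pos cells it departed for interferon (-0.15) and mural genes (1.03). Between the fractions the TFEB effect differed for MHC class II (0.56), dissociation (0.31), fibroblast (0.73), lipid (-0.15), lysosomal hydrolase (-0.19), lysosomal membrane (-0.11) and glycolysis genes (-0.19) (CCR2pos minus CCR2neg). Of these 21, lipid handling beyond the cassette in CCR2neg cells was the 1 called with an estimated correlation. With the animal block 32 genes differed beyond the cassette in CCR2neg cells.

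Lower MHC class II expression in CCR2neg mac-TFEB than CX3CR1-Cre cells (list median -0.92) was tested against 3 technical explanations, and unequal numbers of animals with Xist were argued against, since with a sex term the median was -1.01 (camera adjusted p = 3.5e-04 with an estimated correlation) and in libraries with Xist alone -1.15. Another sequence of chromosome 17's H2 region was argued against by Ciita on 16 (-1.0 ± 0.22) and Cd74 on 18 (-1.18 ± 0.19). Fewer dendritic cells were argued against by their list's median of 0.34. That list's mean log2 CPM was 2.70 ± 0.30 in mac-TFEB and 2.31 ± 0.23 in CX3CR1-Cre (SD), although its Batf3 fell (-1.08 ± 0.19). A candidate biological explanation is that higher TFEB lowers MHC class II transcripts, but the list's median rose by 0.37 from TFEB-TG Cre-neg to mac-TFEB and by 0.80 with Cre in TFEB-wt cells. It was at -0.50 for the cassette alone (adjusted p = 0.300 with an estimated correlation) and -0.38 beyond it (0.266), and the cassette, its insertion and the parentage of the animals stay untested.

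Splits into groups of the same sizes were refitted, moving whole animal labels between genotypes or libraries between groups. Cre in TFEB-TG stands for mac-TFEB against TFEB-TG Cre-neg. Brackets give the splits calling as many genes as the real one, the real count and the highest other. Chance stays open for the fractions in CX3CR1-Cre cells (1 of 100, 102, 3), as only 9 other splits kept label pairs. The same holds for CX3CR1-Cre in CCR2neg (1 of 100, 333, 78) and CCR2pos cells (3 of 100, 1, 1). Chance could be excluded for the cassette in CCR2pos (1 of 100, 4, 3) and TFEB in CCR2neg cells (1 of 100, 176, 106). With the animal block it could be for the effect beyond the cassette in CCR2neg cells (1 of 100, 32, 16). Of 100 splits for TFEB in CCR2neg cells, the real one alone had an MHC class II median as far from 0 as -0.92. The highest other was 0.80, but the list was chosen after its result was seen, so chance is not excluded. It could not be excluded for the counts of the cassette in CCR2neg cells (10 of 100, 52, 737), TFEB in CCR2pos cells (5 of 100, 5, 11), the fractions in mac-TFEB cells (2 of 35, 69, 206), Cre in TFEB-TG CCR2neg cells (4 of 35, 20, 988) or Cre in TFEB-TG CCR2pos cells (2 of 35, 2, 11). A split of 737 genes, with TFEB-TG labels 2 to 4 and TFEB-wt label 2 on one side, points to a structure of the samples, whose source was not tested. TFEB-TG label 1, on the other side, holds the Myh6-rich library without which 440 genes were called. The fit with the number as a block called 111. The splits of 206, 988 and 11 genes set labels 1 and 2 against 3 and 4, as Xist does. That points to the animals as the structure, and the blocked counts were 481, 301 and 26. Splits that part as many same-numbered pairs as the real one called at most 11 genes for CX3CR1-Cre in CCR2neg cells and 0 for the other 5 comparisons within a genotype, where edgeR's real counts were 102, 69, 1, 20 and 2. Where edgeR's real count was 0, with unadjusted counts and other tools given in the text, 100 of 100 splits called as many. The highest other was 1 and 1 beyond the cassette (CCR2neg and CCR2pos) and 0 for the difference of fractions. With the block it was 0 beyond the cassette in CCR2pos cells and 3 for the difference of fractions. For the blocked counts within a genotype the 16 or 8 splits are too few for a share under 0.05. Real values and highest others were 552 and 5, 965 and 204 and 134 and 0 over 16 splits (fractions in CX3CR1-Cre, then CX3CR1-Cre in CCR2neg and CCR2pos), and 481, 301 and 26 against 0 over 8, the real split being 1 of each.

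Counts of lists called by camera at the preset correlation were reached by other splits more often. The effect beyond the cassette in CCR2neg cells had the only share under 0.05 (3 of 100, 12, 13). Chance cannot be excluded among so many tests. It could not be for the cassette in CCR2neg cells (89 of 100, 3, 20), the cassette in CCR2pos cells (72 of 100, 5, 15), TFEB in CCR2neg cells (23 of 100, 9, 15), TFEB in CCR2pos cells (67 of 100, 4, 11), the effect beyond the cassette in CCR2pos cells (49 of 100, 2, 7) and the difference of fractions (11 of 100, 7, 12). Nor could it be for the fractions in CX3CR1-Cre (6 of 100, 10, 12) and mac-TFEB cells (19 of 35, 8, 17). The same held for CX3CR1-Cre in CCR2neg (15 of 100, 13, 18) and CCR2pos cells (25 of 100, 9, 16). It held for Cre in TFEB-TG CCR2neg (26 of 35, 5, 14) and CCR2pos cells (3 of 35, 10, 12).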

How the results depend on the processing

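The sex term, the libraries with Xist, the fit without the 2 libraries that stood apart, list tests with the block, TFEB calls left under other tools or with a library left out and the comparison of mac-TFEB with TFEB-TG Cre-neg were chosen after seeing the data. The other alternatives were planned.

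No named gene or list with a call reversed its direction. Higher and lower calls changed places as the larger part for the cassette in CCR2neg (1 and 0 in its libraries alone), TFEB in CCR2neg (643 and 708 by limma-voom, 404 and 406 with Xist), TFEB in CCR2pos (6 and 3 with the sex term, 15 and 10 with Xist), Cre in TFEB-TG CCR2neg (35 and 50 by DESeq2, 94 and 115 with the block and without the 2 libraries) and Cre in TFEB-TG CCR2pos cells (9 and 17 with the block), and in some fits without 1 library. DESeq2 size factors and the stricter filter, run without a block, kept the counts of the comparisons within 1.5 times of the main count. The unfiltered fit says nothing, since the filter removed none. Of the genes named, DESeq2 size factors ended 4 calls, the stricter filter 4, DESeq2's test 2 with 8 gained, limma-voom 18 with 4 gained, and the random effect 5 with 12 gained. The blocks ended 3 with 22 gained, the fit to a comparison's libraries alone 63 with 3 gained and the fit without the 2 libraries that stood apart 29 with 0 gained. With the sex term 1 were gained and none lost, and in libraries with Xist 3 were lost and 1 gained. Leaving out 1 library ended a call in 374 cases, added 1 in 2 and changed none in 2228. Of the list results, 72 lost their call with an estimated correlation and 63 by fry. The animal block or number block ended 3 and added 15.

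Counts of called genes that moved by more than 1.5 times follow, with the TFEB calls left after removal of cassette calls as left counts (CCR2neg and CCR2pos). Causes were not tested. DESeq2's Wald test gave 288 for the cassette, 318 for TFEB and 2 for the effect beyond the cassette in CCR2neg cells. In CCR2pos cells it gave 14 for TFEB and 11 for CX3CR1-Cre. It gave 210 and 181 for the fractions in CX3CR1-Cre and mac-TFEB and 85 and 5 for Cre in TFEB-TG CCR2neg and CCR2pos cells. Left were 260 and 8. Limma-voom with quality weights gave 102 for the cassette in CCR2neg, 1351 for TFEB in CCR2neg, 9 for TFEB in CCR2pos, 197 for the fractions in CX3CR1-Cre, 287 for the fractions in mac-TFEB, 13 for CX3CR1-Cre in CCR2pos and 13 for Cre in TFEB-TG CCR2neg cells. Left were 1286 and 5. The random effect of genotype and number gave 113, 408 and 3 for the cassette, TFEB and the effect beyond the cassette in CCR2neg cells. It gave 407 and 348 for the fractions in CX3CR1-Cre and mac-TFEB. In CCR2neg and CCR2pos cells it gave 977 and 20 for CX3CR1-Cre and 138 and 7 for Cre in TFEB-TG. Left were 363 and 3. Fits to the libraries of a comparison alone gave 1 for the cassette in CCR2neg, 71 for TFEB in CCR2neg, 165 for the fractions in CX3CR1-Cre, 25 for the fractions in mac-TFEB, 6 for Cre in TFEB-TG CCR2neg and 1 for Cre in TFEB-TG CCR2pos cells. The sex term gave 285 for the cassette in CCR2neg, 428 for TFEB in CCR2neg and 9 for TFEB in CCR2pos cells. Left were 351 and 5. Libraries with Xist alone gave 483 and 14 for the cassette and 810 and 25 for TFEB in CCR2neg and CCR2pos cells. Left were 565 and 18. Without the 2 libraries that stood apart the counts were 448 for the cassette in CCR2neg and 50 for the fractions in CX3CR1-Cre and 6 for the blocked effect beyond the cassette in CCR2neg cells. Left were 96 and 0. Drawing the cassette list at an unadjusted p under 0.05 left 97 and 0 TFEB calls, and drawing it from either fraction left 162 and 1.

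The animal block gave 32 for the effect beyond the cassette in CCR2neg cells and 552 and 481 for the fractions in CX3CR1-Cre and mac-TFEB. In CCR2neg and CCR2pos cells it gave 965 and 134 for CX3CR1-Cre and 301 and 26 for Cre in TFEB-TG. Across genotypes samples share only a number. Same-numbered pairs correlated by -0.112, -0.149, -0.169 and -0.0915 on average in the 4 comparisons of TFEB-TG with TFEB-wt. The block on that number gave 111 and 10 for the cassette and 310 and 12 for TFEB in CCR2neg and CCR2pos cells. Left were 271 and 4. On simulated data the number block made more false calls than the fit without it.

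Leaving out each library in turn gave 6 to 440 and 59 to 260 for the cassette and TFEB in CCR2neg cells. The fractions gave 46 to 106 in CX3CR1-Cre and 36 to 80 in mac-TFEB cells. CX3CR1-Cre gave 195 to 388 in CCR2neg and 1 to 2 in CCR2pos cells, and Cre in TFEB-TG 7 to 32 and 1 to 2. Ranges with the animal block were 5 to 45 and 0 to 1 beyond the cassette in CCR2neg and CCR2pos cells. They were 0 to 14 for the difference of fractions and 366 to 654 and 278 to 396 for the fractions in CX3CR1-Cre and mac-TFEB. They were 59 to 139 for CX3CR1-Cre in CCR2pos and 151 to 303 and 8 to 20 for Cre in TFEB-TG CCR2neg and CCR2pos cells. TFEB calls left ranged over 52 to 244 in CCR2neg and 0 to 1 in CCR2pos cells. The other counts stayed within 1.5 times of their main value whichever library was left out. Depth was at least 13797484 counts per library and limited values of genes near the file's own floor of about 1 CPM, such as Gfi1b in TFEB-wt cells.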

Other observations

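All tests in this part were chosen after seeing the results they bear on.

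Within TFEB-TG animals, 4 mac-TFEB libraries were set against 4 Cre-neg libraries of the same labels, both with the cassette. In CCR2neg cells Tfeb was 3.15 ± 0.47, Duoxa2 4.28 ± 0.56 and the T cell co-receptor gene Cd4 1.57 ± 0.26, all higher with Cre. The complement gene C6 (-3.17 ± 0.56), the lubricin gene Prg4 (-2.90 ± 0.53) and the stress-induced Nupr1 (-1.05 ± 0.14) were lower (edgeR adjusted p of the 6 from 6.3e-05 to 0.00831). All 6 kept their call whichever library was left out. Ctsd (0.17 ± 0.18), Gpnmb (0.50 ± 0.45), Lipa (0.03 ± 0.12) and Ccr2 (-0.30 ± 0.36) were not called, and Cx3cr1 was 0.58 ± 0.21 (edgeR adjusted p = 0.367, 0.00213 with the animal block). Monocyte genes were lower with a median of -0.66 (camera adjusted p = 4.3e-12, adjusted p = 0.0283 with an estimated correlation) and MHC class II genes higher with 0.37 (camera adjusted p = 4.9e-06, adjusted p = 0.323 with an estimated correlation). Camera also called resident macrophage (-0.40), cardiomyocyte (-0.99) and proliferation genes (0.36), none with an estimated correlation. The mitochondrial share was 0.791 to 1.30% without and 0.643 to 0.753% with Cre, and mean log2 CPM went from 2.03 to 1.01 for neutrophil and from 2.23 to 2.70 for dendritic cell genes, and no test set these apart. EdgeR called 20 genes, and the count was 32 and 7 without TFEB-TG Cre-neg libraries 1 and 2 and 10 without mac-TFEB library 1. With the animal block it called 301, and 151, 161 and 187 without mac-TFEB libraries 1, 2 and 3.

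In CCR2pos cells the same comparison called 2 genes, Duoxa2 (4.84 ± 0.59, edgeR adjusted p = 2.5e-05) and the catenin gene Ctnnd2 (1.96 ± 0.37, 0.0454), both higher in mac-TFEB. Tfeb was 2.03 ± 0.44 (edgeR adjusted p = 0.215, 3.2e-04 with the animal block), Cx3cr1 0.14 ± 0.21 and Ccr2 -0.41 ± 0.35. Monocyte genes were lower by a median of -0.38 (camera adjusted p = 2.1e-12, adjusted p = 0.0239 with an estimated correlation). The others of 10 lists called by camera were not called that way. Neutrophil genes fell from a mean log2 CPM of 1.21 to 0.54, and the mitochondrial share was 0.612 to 0.886% without and 0.537 to 0.627% with Cre. The count was 1 without TFEB-TG Cre-neg library 1, 3 or 4 or any mac-TFEB library, and with the block 26 (9 higher and 17 lower) and 16, 9 and 14 without TFEB-TG Cre-neg libraries 1, 2 and 4 and 14 and 8 without mac-TFEB libraries 1 and 2.

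Genes next to Gfi1b on chromosome 2 set the TFEB-TG libraries apart, and in the stretch from Olfm1 to Gfi1b 7 genes had a median of -1.08 over the 4 comparisons of TFEB-TG with TFEB-wt, 6 of them were lower in each, and the 16 flanking genes had medians of 0.22, 0.08, 0.06 and 0.08 and 0 edgeR calls. The hypothesis below had allowed flanks within 0.2 of 0, and 1 of the 4 lies past that. The 5 called genes of that stretch compare with at most 4 in 12616 windows of as many genes elsewhere. A rise in TFEB as the cause was argued against, since from TFEB-TG Cre-neg to mac-TFEB the 7 genes had a median of 0.26. One copy of the segment that is lost or silent, with the cassette placed at or near it, may account for the values, as a hypothesis that read alignments could test and that is not told apart here from linked variants of the animals.

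Tfeb above the TFEB-wt level in TFEB-TG Cre-neg cells may come from Cre-expressing cells left in the sort or from transcription through the stop sequence. Taking the libraries of a label as 1 animal, Tfeb would need at least 16.2% of leftover cells in CCR2pos and 4.93% in CCR2neg cells, while Duoxa2, steady in Cre libraries, allows at most 9.04 and 12.2% (highest upper 95% limits, of counting alone). The limits rest on 1 gene of 1 to 12 reads, below the file's floor, so the explanations cannot be told apart in either fraction. In both fractions 4 of 4 TFEB-TG Cre-neg libraries held more Tfeb than every TFEB-wt Cre-neg library, as either explanation would give.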
